A study of Danio rerio with 6 samples.

How the data were processed

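RNA was measured in cells sorted from the eyes of zebrafish (Danio rerio) larvae at 5 days post-fertilization. The larvae carried thrb:tdTomato, a red fluorescent reporter under the control of thrb, the gene of the thyroid hormone receptor that marks red cones. Red-fluorescent cells were collected by fluorescence-activated cell sorting from wild-type (WT) larvae and from larvae labelled samd7−/−, which were bred from parents both homozygous for the stl888 allele. Each of the 3 libraries per genotype came from its own clutch, so the libraries of a group are separate biological samples. Per the labels' protocols, a library used 40 to 50 eyes of 20 to 25 larvae, 10000 to 25000 sorted cells and 300 pg of RNA with integrity numbers between 7.4 and 8.4. Complementary DNA was made with a kit for ultra-low input and amplified for 14 cycles, the sequencing library was amplified for 15 cycles, and paired-end reads of 150 bases were made on a NovaSeq instrument. WT and mutant-labelled clutches had different parents, and genotype and parental line are therefore confounded. Only part of each clutch was genotyped, per the labels.

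The authors deposited a table of 14781 genes with 1 column per library, a mean per genotype, a log2 fold change and an adjusted p-value. Trim Galore 0.6.1, STAR 2.7.2b, HTSeq 0.9.1, DESeq2 1.34.0 and R 4.1.3 and the danRer10 build of the genome are named in the submitters' processing notes. The gene annotation, the strand setting and the handling of reads shared between similar genes are not given in the sources used here. The library columns of the deposited table hold a signal that is a read count divided by a size factor for each library, referred to below as normalized counts. This was read from the values: within a library, 100% of the values above 0 were whole multiples of the smallest step to within 0.01 read, so that whole reads could be recovered. The deposited means matched the means of the library columns to within 0.00037, and 99.976% of the deposited log2 fold changes had the sign of mutant-labelled minus WT. The adjusted p-values and log2 fold changes of the authors' deposited table are quoted only where they are named as the authors'.

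The recovered reads summed to 15621680, 18911482 and 13435570 in WT libraries 1 to 3 and to 18418834, 18956650 and 20369266 in libraries 1 to 3 labelled samd7−/−. With 3 counts taken as the limit that a count of 0 allows, the limit was between 2.24 and 3.99 normalized counts per library. No molecular identifiers are described and 14 plus 15 cycles of amplification were used, so such limits cover counting error only. Of these genes 2264 were at 0 in all 6 libraries. Another 11 entries carried date-like names, as left by spreadsheet software, and were not matched to any list. Symbols were taken as the table gives them, and 12660 of them matched an NCBI gene identifier. The gene table used for names and older symbols describes assembly GRCz12tu, another build than that of the authors, so no coordinates are given.

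The design fixed before the data were examined named limma for normalized values and edgeR for raw counts, and limma was used because the table holds normalized counts. Values were transformed as log2(value + 1), and genes with at least 10 normalized counts in at least 3 of the 6 libraries were kept. Genotype was the only term of the model, and the empirical Bayes step used a mean-variance trend and its robust option (limma 3.58.1 in R 4.3.3). A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are differences of mean log2(value + 1). The added 1 makes them understate the change of low genes, while taking means of logs can place them above or below the log2 ratio of the mean levels where libraries differ widely. For tgfa the value was 6.86, against 5.68 with edgeR, and for exorh 6.23, against 6.75. Data were simulated from the means and spread of these libraries, with 9355 genes passing the filter and 100 genes changed at each fold size. The changed genes were drawn from those with a mean of at least 100 normalized counts, so the shares below do not cover lower genes. There limma recovered 19% of 2-fold changes and 66% of 4-fold changes of mutant-labelled against WT, and 4.49% of its calls were false. The recovered reads were also tested with edgeR 4.0.16 (quasi-likelihood test, TMM factors), which recovered 15% and 64% of these changes, and with DESeq2 1.42.0.

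Opsin composition was the share of each opsin class in the summed visual opsin values of a library, compared by a two-sided exact permutation test, whose smallest possible p for 3 against 3 libraries is 0.1. For 35 gene lists written before the data were examined, members were matched by symbol (945 of 1148) or older symbol (53), and 150 symbols were not matched. Lists with at least 3 tested members were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. In the simulated data, a list of shifted genes reached an adjusted p of 0.000266 with the preset and of 0.345 with the estimated correlation, and 0 of the null lists was called. The simulated genes were drawn independently of each other, so this does not show how either setting behaves where list members are correlated. In the real libraries the estimated correlation ranged from -0.132 (blue cones) to 0.442 (outer segment). The lists covered visual opsins, markers of red, green, blue and UV cones and of rods, cone phototransduction, photoreceptor transcription factors, non-visual opsins, pineal and melatonin genes, outer segment structure, the visual cycle, the photoreceptor synapse, Polycomb proteins, hox genes, transcription factors of other tissues, thyroid and retinoid signalling, p53 and apoptosis, the unfolded protein response, immediate early genes, the circadian clock, and glycolysis and creatine. They also covered markers of bipolar, horizontal, amacrine and ganglion cells, Müller glia, retinal pigment epithelium, lens, leukocytes, erythrocytes, vessels and mesenchyme, surface epithelium, muscle and dividing cells.

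The genes named were fixed by a rule before the data were examined. Named were samd7, thrb and the 9 visual opsins, then the 10 largest increases and the 8 largest decreases among called genes with a mean of at least 50 in the higher group, no overlap between the genotypes and no clone-style name. From each list with called members up to 4 with the highest mean were named, and from each other list the member with the highest mean. A gene named outside this rule is said to have been chosen after its values were seen. Alternatives fixed beforehand were DESeq2, TMM, upper-quartile and library-total scaling, scaling without the 50 most abundant genes, no filter and a filter at 50, pseudocounts of 0.5 and 5, the replicate number as a block, stricter thresholds and leaving out each library. The edgeR test, a fit with the log2 level of rho in each library as a covariate, and other scalings for the gene lists were added after the data were seen. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.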

Results

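RNA was sequenced from thrb:tdTomato-positive cells of zebrafish eyes at 5 days post-fertilization to ask how the stl888 allele of samd7, which encodes a photoreceptor protein of the Polycomb family, relates to the identity of cones and the rule that a photoreceptor holds 1 opsin. There were 3 libraries from WT larvae and 3 from larvae labelled samd7−/−, each from its own clutch. Recovered reads per library ranged from 13435570 to 18911482 in WT and from 18418834 to 20369266 in the other group. The 10 most abundant genes took 27.1% to 28.6% of reads in WT and 20.0% to 26.2% in the libraries labelled samd7−/−. Libraries of a genotype differed by more than counting noise, with a chi-square per degree of freedom between 53.7 and 172, a measure that leaves out the noise of amplification. The first 2 principal components held 29.0% and 22.8% of the variance. On the first, WT libraries 1 to 3 lay at -24.9, -88.9 and -44.9, and libraries 1 to 3 labelled samd7−/− at 22.1, 24.4 and 112. Library 3 labelled samd7−/− also stood apart from the others of its group on the second (-75.0 against 66.1 and 49.6), as did WT library 2 (-75.5 against 29.6 and 5.15). The chi-square per degree of freedom of that mutant-labelled library against the others of its group was 172 and 159, against 96.7 between those. Because the genotypes were bred from different parents, each difference below is between lines as well as between genotypes.

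The targeted gene was read first. The level of samd7 was 7683 ± 896 normalized counts in WT (SD, n = 3, as for all levels below) and 24329 ± 543 in the libraries labelled samd7−/−, a rise of 1.67 on the log2 scale (SE 0.16, adjusted p = 3.35e-05). The transcript was thus higher, not lower, in all 3 libraries labelled samd7−/−. The labels do not say how the stl888 allele affects the transcript, so this level does not check the genotype, and the group is called the mutant-labelled libraries throughout. The level of thrb, the gene whose regulatory sequence drives the reporter, was 14152 ± 2052 in WT and 10677 ± 604 in the mutant-labelled libraries, with a log2 difference of -0.40 that did not pass the test over all genes (SE 0.16, adjusted p = 0.200). Its limma p before adjustment was 0.0300, with a 95% interval of the log2 difference from -0.75 to -0.04. The genotypes did not overlap, as was so for 24.5% of tested genes. A fall of thrb is thus not excluded.

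Among the visual opsins, the main red-cone opsin fell, the second red-cone opsin rose, and both measured green-cone opsins were at 0 in the mutant-labelled libraries. The UV opsin had the largest rise of the visual opsins, though limma did not call it over all genes. The red opsin opn1lw2 went from 1559230 ± 116919 to 673457 ± 292047 (log2 change -1.29, SE 0.23, adjusted p = 0.00510). Its neighbour opn1lw1 went from 2027 ± 631 to 24932 ± 20660 (log2 change 3.29, SE 0.65, adjusted p = 0.0459). The green opsin opn1mw1 had 69558 ± 46866 in WT and 0 in each mutant-labelled library, at least 28454-fold lower when 3 counts per library are set as the limit (adjusted p = 5.58e-10). This bound rests on the WT mean, and WT libraries 1 to 3 differed widely, with 27237, 61511 and 119926. For opn1mw2 the WT level was 1658 ± 1156 and the mutant-labelled level 0, at least 678-fold lower (adjusted p = 0.000278). The remaining green opsins opn1mw3 and opn1mw4 were at 0 in all 6 libraries. The UV opsin opn1sw1 had 28128 ± 21368 in WT and 1167970 ± 456898 in the mutant-labelled libraries, a log2 difference of 5.91 with no overlap that did not pass limma's threshold (SE 1.11, adjusted p = 0.0720). For this gene edgeR gave an adjusted p of 0.00919 and DESeq2 one of 6.33e-12, and limma one of 0.00640 when adjusted over the visual opsins alone. Its log2 difference moved to 4.80 without WT library 1, where the visual opsin gene opn1sw1 passed (adjusted p = 1.81e-06), and to 6.54 without WT library 3. The blue opsin opn1sw2 had 7636 ± 3556 and 33812 ± 29905 (log2 difference 1.90, adjusted p = 0.230). Its log2 difference moved to 1.21 without mutant-labelled library 3 and to 2.42 without mutant-labelled library 1. Its adjusted p ranged over the alternatives from 0.000105, with rho as a covariate (chosen after the data were seen), to 0.435 without mutant-labelled library 2. The rod opsin rho had 45709 ± 32348 and 23374 ± 26428 (log2 difference -1.13, adjusted p = 0.715). For rho the log2 difference moved to -2.06 without WT library 1 and to -0.59 without WT library 3. Of the 7 visual opsins tested 4 passed over all genes and 6 passed when adjusted over the list alone, and the list was not called as a whole by camera (median -1.13, adjusted p = 0.472). Over its alternatives, the adjusted p of opn1sw1 ranged from 6.33e-12 to 0.203, the latter without mutant-labelled library 2. Without that library the adjusted p of opn1lw2 was 0.0546, and the call of opn1lw1 was lost in 6 of 18 settings, with an adjusted p up to 0.194 without WT library 2. The log2 change of opn1lw1 moved to 2.63 without mutant-labelled library 2 and to 3.95 without mutant-labelled library 1. No sequences of the opn1lw and opn1mw copies were compared here. How reads shared between copies were counted is not given in the sources used, so the split of reads between members is uncertain.

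Opsin composition, which does not depend on library scaling, had a lower red and a higher UV share in each mutant-labelled library than in any WT library. Red opsins made up 91.4% ± 5.12 of visual opsin signal in WT and 36.4% ± 1.345 in the mutant-labelled libraries, and the UV opsin 1.58% ± 1.14 and 61.1% ± 1.90. Green opsins held 3.98% ± 2.27 in WT and 0% in the mutant-labelled libraries, the blue opsin 0.435% ± 0.163 and 1.55% ± 0.759, and the rod opsin 2.57% ± 1.72 and 1.01% ± 0.777. The groups did not overlap for the red, UV, green and blue classes, for each of which the two-sided exact permutation p was 0.1, the smallest that 3 against 3 libraries allow (adjusted 0.125). For the rod class the exact permutation p was 0.3. Visual opsins together took 9.35% ± 1.35 of normalized counts in WT and 12.0% ± 3.63 in the mutant-labelled libraries.

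**Figure D1:**
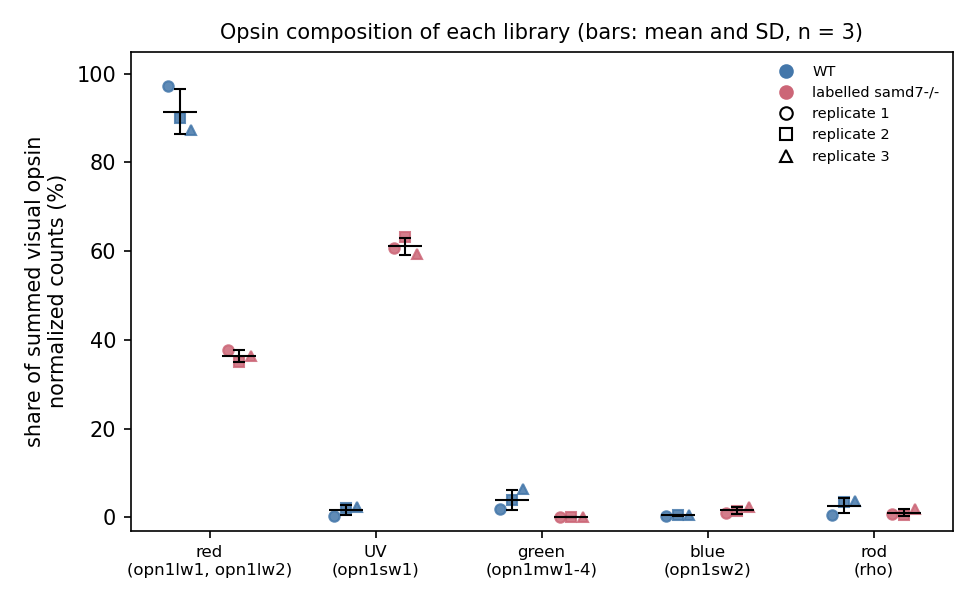
Share of each opsin class in the summed normalized counts of the visual opsins, in percent, for 3 WT and 3 mutant-labelled libraries, with points for libraries and bars for mean and SD. Red opsins averaged 91.4% in WT and 36.4% in the mutant-labelled libraries, while the UV opsin averaged 1.58% and 61.1%.

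The cone arrestins, which end the signal of light-activated opsin, exchanged places. The red- and green-cone arrestin arr3a fell from 492134 ± 121241 to 6695 ± 2174 normalized counts (log2 change -6.23, SE 0.24, adjusted p = 7.30e-09), and the UV- and blue-cone arrestin arr3b rose from 7253 ± 2943 to 511776 ± 156293 (log2 change 6.197, SE 0.33, adjusted p = 6.57e-06). Their sum was 499387 ± 118732 in WT and 518471 ± 157341 in the mutant-labelled libraries. The transcription factor tbx2a, a regulator of UV-cone fate, rose from 2142 ± 363 to 13869 ± 1702 (log2 change 2.701, adjusted p = 2.84e-06), and its paralog tbx2b from 1219 ± 227 to 2620 ± 485 (log2 change 1.105, adjusted p = 0.0124). Of 5 UV-cone genes these 3 rose and 0 fell (4 changed when adjusted over the list alone, median 2.701, camera adjusted p = 8.43e-10, adjusted p = 0.0904 with an estimated correlation). Among 5 blue-cone genes arr3b rose (4 when adjusted over the list alone, median 1.90, adjusted p = 0.151). Of 4 green-cone genes tested both opsins fell (4 over the list alone, median -5.57 and -5.11 with the opsins at their bounds, adjusted p = 8.61e-08, adjusted p = 0.170 with an estimated correlation). Of 7 red-cone genes opn1lw2 and arr3a fell and opn1lw1 rose (6 over the list alone, median -0.40, adjusted p = 0.153). Without WT library 2 the adjusted p of tbx2b was 0.0713.

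**Figure D2:**
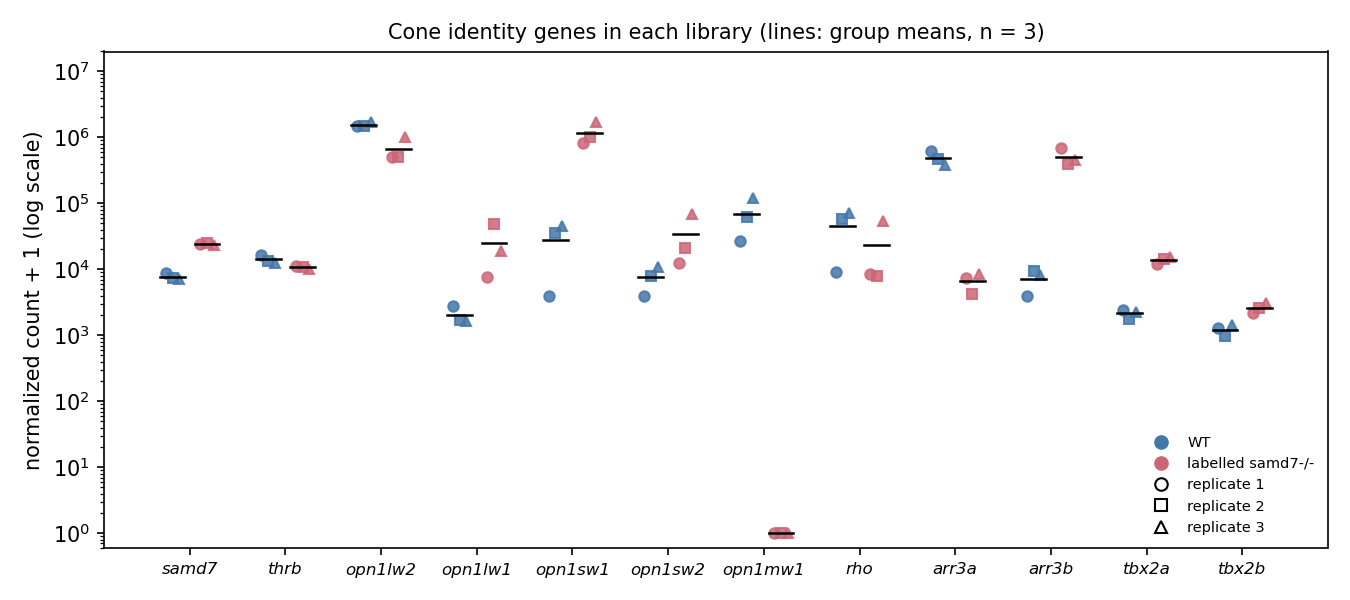
Normalized counts plus 1, on a log scale, of samd7, thrb, visual opsins, arrestins and tbx2 genes in each of the 3 WT and 3 mutant-labelled libraries, with lines at group means. The arrestins lie in opposite order in the genotypes, with arr3a at 492134 in WT and 6695 in the mutant-labelled libraries and arr3b at 7253 and 511776.

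Of 24 transcription factors of photoreceptors tested, 5 rose and 2 fell (11 when adjusted over the list alone, median 0.25, camera adjusted p = 0.211). Besides samd7, tbx2a and tbx2b, the nuclear receptor rorb rose (log2 change 0.83, adjusted p = 0.0431), as did lhx4 (0.78, adjusted p = 0.0476). The nuclear receptor nr2f6b fell (log2 change -1.10, adjusted p = 0.0179), as did mef2cb (-1.21, adjusted p = 0.00305). The genes lhx4 and mef2cb were chosen after their values were seen. Of 35 Polycomb genes 2 rose and 2 fell (4 when adjusted over the list alone, median 0.11, adjusted p = 0.556). These were samd7, the histone-binding rbbp4 (log2 change 1.07, adjusted p = 0.00664) and the chromobox genes cbx7a (-1.46, adjusted p = 0.0184) and cbx8a (-1.08, adjusted p = 0.0240). Of 42 transcription factors of other tissues isl1 and barhl2, which retinal neurons also express, rose (2 over the list alone, median 0.38, adjusted p = 0.115). Of 24 genes of thyroid and retinoid signalling 0 passed with limma, also when adjusted over the list alone (median 0.45, adjusted p = 0.556), the member with the highest level being thrb. Among hox genes too few members passed the filter for a test, and the most abundant, hoxa13b, had 17.2 ± 29.9 and 24.4 ± 42.3. With edgeR the calls of rorb (adjusted p = 0.0702) and nr2f6b (adjusted p = 0.0511) were lost. With 1 library left out the call of rorb was lost, with an adjusted p up to 0.202 (without WT library 2). Calls were likewise lost for nr2f6b (0.0832, without mutant-labelled library 1), cbx7a (0.116) and cbx8a (0.135), both without WT library 2, isl1 (0.130, without mutant-labelled library 1) and lhx4 (0.151, without mutant-labelled library 2).

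Across the transcriptome more genes fell than rose under the authors' scaling. Of 9886 genes tested 511 changed, 125 higher and 386 lower in the mutant-labelled libraries, and 83 and 270 of these changed at least 2-fold. Scaling by library totals instead gave 415 higher and 252 lower, 62.2% against 24.5% higher, with the median of all genes moved by 0.23 on the log2 scale. Among the largest increases were tgfa, a ligand of the EGF receptor (6.01 ± 10.4 to 311 ± 41.0, log2 change 6.86, adjusted p = 0.0151), and exorh, the exo-rhodopsin of the pineal gland (2.53 ± 2.203 to 273 ± 242, log2 change 6.23, adjusted p = 0.0223). The atypical cadherin fat1a rose from 85.1 ± 35.1 to 1151 ± 481 (log2 change 3.76, adjusted p = 0.000374), the protease bace1 from 24.1 ± 21.9 to 373 ± 112 (4.19, adjusted p = 0.00894) and the adhesion molecule jam2a from 156 ± 116 to 1051 ± 588 (2.92, adjusted p = 0.00833). Synapsin syn1 (log2 change 5.18, adjusted p = 0.0370), the helicase ddx28 (6.104, adjusted p = 0.0477) and the opsin kinase grk7b (2.80, adjusted p = 0.0332) rose as well. For tgfa and syn1 edgeR gave smaller log2 changes, 5.68 and 3.84, and it did not call syn1 (adjusted p = 0.102), ddx28 (adjusted p = 0.0581) or grk7b (adjusted p = 0.0791). The decreases included klf15, a transcription factor (4938 ± 607 to 230 ± 112, log2 change -4.54, adjusted p = 3.77e-06), kera, a keratan sulfate proteoglycan known from the cornea (14693 ± 2694 to 667 ± 457, -4.75, adjusted p = 0.00463), and nptx2b, a neuronal pentraxin (840 ± 18.6 to 40.4 ± 20.2, -4.48, adjusted p = 0.000271). The kinase camk2d1 (log2 change -4.22, adjusted p = 2.81e-05) and the transferase ggt5a (975.4 ± 68.2 to 20.9 ± 20.6, -6.63, adjusted p = 0.00363) fell too. With 1 mutant-labelled library of ggt5a at 0, edgeR gave it a smaller log2 change, -5.52. With 1 library left out log2 changes ranged from -7.68 to -4.99 for ggt5a, from 4.37 to 6.63 for syn1, from 6.15 to 8.28 for tgfa, from 2.02 to 3.54 for grk7b and from 5.61 to 7.04 for ddx28. They ranged from 5.48 to 6.69 for exorh, from -5.28 to -4.05 for kera, from 2.29 to 3.49 for jam2a and from 3.75 to 4.86 for bace1. Calls of exorh, tgfa, bace1, ddx28, syn1 and grk7b were lost with 1 library left out, with adjusted p up to 0.128 and 0.189 for exorh and ddx28 (without mutant-labelled library 3). It was 0.0909, 0.130 and 0.143 for tgfa, syn1 and grk7b (without mutant-labelled library 1) and 0.0669 for bace1 (without mutant-labelled library 2). The call of ddx28 was lost in 11 of 17 settings. The number of changed genes was 225 without WT library 2, 279 without mutant-labelled library 1 and 311 without WT library 1, and DESeq2 called 870. Without mutant-labelled library 3, which stood apart, it was 573, with 125 higher and 448 lower.

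**Figure D3:**
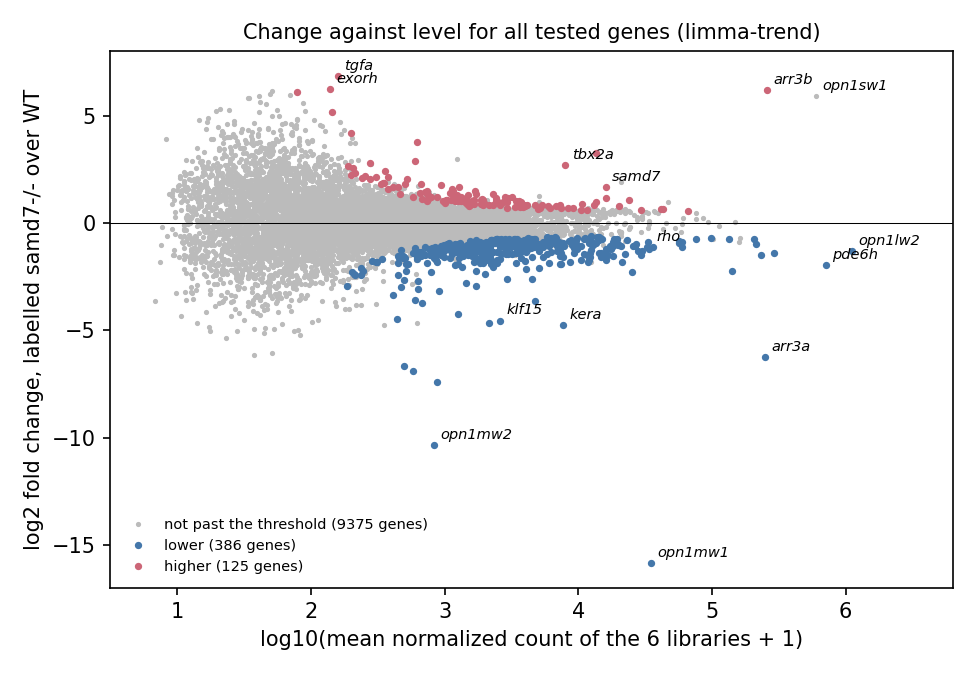
Log2 fold change of mutant-labelled over WT libraries against log10 of the mean normalized count plus 1 for 9886 genes, with 125 higher genes in red and 386 lower genes in blue. The opsin opn1mw1 is the lowest point, and arr3a and arr3b lie apart at high level on opposite sides.

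Genes for light detection and for the photoreceptor synapse were among those that fell, though not all members of a list did. Of 21 cone phototransduction genes 15 fell and 2, arr3b and grk7b, rose (19 when adjusted over the list alone, median -0.94, camera adjusted p = 1.73e-09, adjusted p = 0.230 with an estimated correlation). The inhibitory subunit of cone phosphodiesterase, pde6h, went from 1114830 ± 72719 to 306844 ± 128974 (log2 change -1.96, SE 0.26, adjusted p = 0.00146), and the calcium sensor rcv1 from 284116 ± 14460 to 146701 ± 21492 (-0.96, adjusted p = 0.00175). Of 15 outer segment genes 9 fell and 0 rose (12 over the list alone, median -0.92, adjusted p = 7.88e-10, adjusted p = 0.227 with an estimated correlation), among them the disc rim genes prph2a (log2 change -0.92, adjusted p = 0.00769) and prph2b (-0.83, adjusted p = 0.0143), phosducin pdcb (-1.31, adjusted p = 0.00146) and unc119b (-0.98, adjusted p = 0.00311). Of 16 synapse genes 6 fell and 0 rose (9 over the list alone, median -0.90, adjusted p = 0.000146, adjusted p = 0.227 with an estimated correlation). The exocytosis genes snap25b (log2 change -1.21, adjusted p = 0.000410), cplx4a (-1.29, adjusted p = 0.000531), syt5b (-1.08, adjusted p = 0.00183) and syt5a (-1.05, adjusted p = 0.00201) were the most abundant of these. Of 15 visual cycle genes rbp4l (log2 change -1.48, adjusted p = 0.0407) and abca4a (-1.55, adjusted p = 0.0120) fell. The list had 5 over the list alone, a median of -0.16, a mean of 0.006 and a test pointing down (adjusted p = 0.526). Its median was 0.02 under library totals. Markers of horizontal and amacrine cells and of dividing cells moved the opposite way in the same libraries, with medians of 0.67, 0.65 and 0.76. With 1 library left out calls were lost for pde6h and rbp4l (adjusted p up to 0.114 and 0.132, without mutant-labelled library 3), prph2a (0.0642, without WT library 2), prph2b (0.105, without mutant-labelled library 1) and abca4a (0.0707, without WT library 1).

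Rod genes did not pass the test. Of 18 rod genes 0 rose and 0 fell with limma (1 changed when adjusted over the list alone, median -0.72, camera adjusted p = 0.211), and rho per library was 9063, 57776 and 70290 in WT and 8408, 7825 and 53889 in the mutant-labelled libraries. The rod median lay 0.215 above that of the cone phototransduction genes on the log2 scale, a difference that was not itself tested. A score per library, the median over a list of each gene's log2 value less its mean, was tested instead. The rod score less the cone score was 0.054 higher in the mutant-labelled libraries (exact permutation p = 0.9).

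Lists of horizontal, amacrine and dividing cells were higher in the mutant-labelled libraries with the preset correlation. Of 19 horizontal cell genes 5 rose and 1 fell (10 when adjusted over the list alone, median 0.67, camera adjusted p = 0.000553, adjusted p = 0.170 with an estimated correlation). The transcription factors barhl2 (log2 change 1.002, adjusted p = 0.0102) and isl1 (0.75, adjusted p = 0.0331) and the small GTPase rem1 (1.03, adjusted p = 0.0145) rose and sept4a fell (-0.92, adjusted p = 0.0125). Both onecut1 (1.31) and cx52.9 (0.84), chosen after their values were seen, rose too. Of 20 amacrine cell genes 4 rose and 0 fell (4 over the list alone, median 0.65, adjusted p = 0.00508, adjusted p = 0.170 with an estimated correlation). These were barhl2, pax6a (log2 change 0.94, adjusted p = 0.0363), pax6b (1.22, adjusted p = 0.0194) and tfap2b (1.59, adjusted p = 0.00262). Of 42 genes of dividing cells 5 rose and 0 fell (18 over the list alone, median 0.76, adjusted p = 8.47e-12, adjusted p = 0.175 with an estimated correlation), namely mki67 (2497 ± 237 to 4255 ± 96.9, log2 change 0.77, adjusted p = 0.0222), top2a (0.99, adjusted p = 0.0199), nusap1 (1.06, adjusted p = 0.0291), the chromatin gene hmgn2 (0.67, adjusted p = 0.0446) and, chosen after its values were seen, aurkb (1.33, adjusted p = 0.0169). With edgeR the calls of hmgn2 (adjusted p = 0.0791) and nusap1 (adjusted p = 0.0555) were lost. With 1 library left out all of these calls except those of barhl2 and tfap2b were lost. The adjusted p reached 0.0747 for sept4a, 0.130 for isl1, 0.231 for hmgn2 and 0.0810 for aurkb (without mutant-labelled library 1). It reached 0.0827, 0.0786, 0.112, 0.110 and 0.136 for rem1, pax6b, mki67, top2a and nusap1 and 0.0760 and 0.146 for onecut1 and cx52.9 (without WT library 2), and 0.151 for pax6a (without mutant-labelled library 2).

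Other cell type lists did not pass camera, but those of bipolar cells, ganglion cells and Müller glia had medians above 0 and came near its threshold. A difference between these lists and those of horizontal, amacrine and dividing cells is therefore not shown. Of 21 bipolar cell genes isl1 rose and lrit3a fell (log2 change -1.08, adjusted p = 0.0476). In WT lrit3a had 7281 ± 1467 normalized counts, against a median of 115 over the list, so its fall is not shown to be one of bipolar cells. The list had 4 over the list alone and a median of 0.86 (camera adjusted p = 0.0622). Of 18 ganglion cell genes barhl2 and robo2 rose (robo2 0.87, adjusted p = 0.0287; 2 over the list alone, median 0.65, adjusted p = 0.0545). Of 28 Müller glia genes glula rose (log2 change 1.06, adjusted p = 0.0102) and slc1a2a (-1.35, adjusted p = 0.00184) and rgra (-1.42, adjusted p = 0.00849) fell (7 over the list alone, median 0.38, adjusted p = 0.0544). Of 12 pigment epithelium genes the clock gene bhlhe40 fell (1 over the list alone, median 1.09, adjusted p = 0.556). With limma 0 genes passed, also when adjusted over the list alone, among 24 lens genes (median -1.16, adjusted p = 0.145), 20 leukocyte genes (0.44, adjusted p = 0.556) and 5 erythrocyte genes (0.85, adjusted p = 0.472). The same held for 17 genes of vessels and mesenchyme (-0.88, adjusted p = 0.804), 23 surface epithelium genes (-0.94, adjusted p = 0.206) and 8 muscle genes (-0.75 with a mean of 0.27 and a test pointing down, adjusted p = 0.424). The member of each with the highest level had 386 ± 218 and 293 ± 289 (crybb1), 1229 ± 344 and 1288 ± 484 (ccl34b.1), 650 ± 226 and 1136 ± 251 (cahz), and 626 ± 502 and 857 ± 436 (cldn5b) normalized counts. For krt4 these were 4345 ± 5356 and 2192 ± 2038, and for eno3 8847 ± 5087 and 4221 ± 1922. With edgeR the call of lrit3a was lost (adjusted p = 0.102). Calls of lrit3a and robo2 were lost with 1 library left out (adjusted p up to 0.191 without WT library 2 and 0.132 without mutant-labelled library 1), as were those of glula (0.0632, without WT library 1) and rgra (0.0510, without WT library 3).

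Non-visual opsins and pineal genes moved in both directions. Of 13 non-visual opsins exorh rose and rgra fell (4 when adjusted over the list alone, median 0.73, adjusted p = 0.926). Of 10 genes of pineal and melatonin function tbx2b and exorh rose and the melatonin enzyme gene asmt2 fell from 1095 ± 358 to 168 ± 70.8 (log2 change -2.72, adjusted p = 0.00147; 3 over the list alone, median -0.31 with a mean of 0.09 and a test pointing down, adjusted p = 0.757).

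Clock, stress and metabolic genes changed as well. Of 28 circadian genes 11 fell and 0 rose (17 when adjusted over the list alone, median -0.77, camera adjusted p = 1.73e-09, adjusted p = 0.170 with an estimated correlation). The repressors bhlhe40 (26907 ± 1912 to 9294 ± 603, log2 change -1.53, adjusted p = 5.74e-05), nfil3-6 (-1.71, adjusted p = 0.000748), nr1d1 (-1.28, adjusted p = 0.00146) and nr1d2a (-1.04, adjusted p = 0.00250) were the most abundant. The immediate early list also held heat shock genes. Of its 33 genes, which cell dissociation can induce, 3 fell (7 over the list alone, median -0.34, adjusted p = 0.0121, adjusted p = 0.560 with an estimated correlation). These were the phosphatase gene dusp5 (log2 change -1.89, adjusted p = 9.17e-05), nr4a1 (-1.16, adjusted p = 0.0477) and si:ch211-199o1.2 (-2.98, from -3.67 to -2.27 with 1 library left out, adjusted p = 0.00851). The last is an older symbol of the heat shock gene hspa1b. Of 22 genes of p53 and apoptosis gadd45ba (log2 change -2.25, adjusted p = 3.20e-05), mdm2 (-1.13, adjusted p = 0.0212) and sesn1 (-0.76, adjusted p = 0.0477) fell (7 over the list alone, median -0.13, 0.10 under library totals, adjusted p = 0.0310, adjusted p = 0.227 with an estimated correlation). Of 30 genes of the unfolded protein response herpud1 fell (log2 change -1.26, adjusted p = 0.00844; 2 over the list alone, median 0.32, adjusted p = 0.151). Of 28 genes of glycolysis and creatine 2 rose and 3 fell (10 over the list alone, median 0.04, adjusted p = 0.905). The creatine kinases ckbb (416948 ± 43456 to 162526 ± 39197) and ckmt2a (log2 change -0.71, adjusted p = 0.0407) and tpi1a (-1.27, chosen after its values were seen) fell. The enzyme genes eno1a (1.15, adjusted p = 0.00501) and pgam1a (1.005, adjusted p = 0.0161) rose. Of the 34 lists tested, 11 were called with the preset correlation and 0 with an estimated one, and other groupings of the 6 libraries into 3 and 3 called up to 9 lists. The test fry, which asks whether members move on balance in a single direction and does not compare them with other genes, called 12 lists. These were 9 of the 11 and the lists of visual opsins (adjusted p = 0.0189), red cones (adjusted p = 0.0177) and blue cones (adjusted p = 0.0177). It did not call the p53 (adjusted p = 0.0858) and immediate early lists (adjusted p = 0.254), and in its mixed form, for change in either direction, it called 26. The gene list p53_apoptosis was not called under library totals (adjusted p = 0.0617) or without the low-value filter (adjusted p = 0.0528). The gene list immediate_early_dissociation was not called under library totals (adjusted p = 0.0549). Leaving out 1 library ended these list calls too, with adjusted p up to 0.0708 (without WT library 2) and 0.156 (without mutant-labelled library 3). With edgeR the calls of nr4a1 (adjusted p = 0.0773) and ckmt2a (adjusted p = 0.0958) were lost. With 1 library left out calls were lost for sesn1 and pgam1a (adjusted p up to 0.228 and 0.0875, without WT library 2), nr4a1, ckmt2a, herpud1 and tpi1a (0.181, 0.197, 0.0509 and 0.117, without WT library 1) and mdm2 (0.0901, without mutant-labelled library 1).

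**Figure D4:**
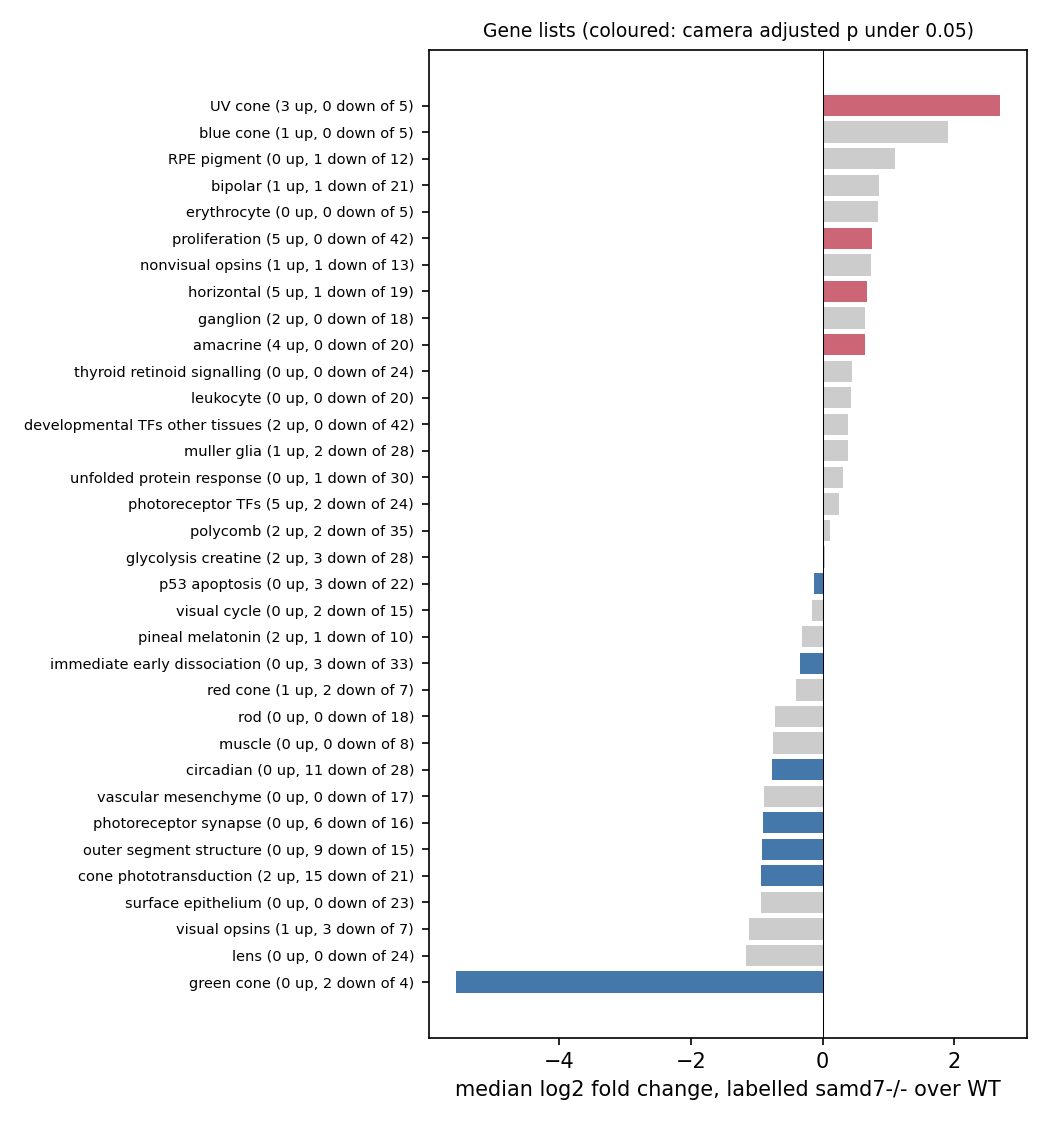
Median log2 fold change of mutant-labelled over WT libraries for each of 34 gene lists, with the members higher and lower of those tested, coloured where camera with the preset correlation called the list. The UV-cone list has the highest median, 2.701, and the green-cone list the lowest, -5.57; under library totals the medians of the p53 and visual cycle lists lie above 0.

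The authors' deposited table gave its own comparison of the same libraries. At its adjusted p under 0.05 it called 343 genes higher and 563 lower, including all 511 called here in the same direction and 359 further genes among those tested. Signs were the same for 93.2% of tested genes. In the authors' deposited table samd7 had a log2 fold change of 1.66 (adjusted p = 1.43e-27) and arr3b one of 6.14. There opn1sw1, not called by limma, had 5.38 (adjusted p = 8.62e-12). Among genes called here, edgeR on the recovered reads also called 423 in the same direction (103 higher and 328 lower in all), and DESeq2 510.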

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

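The tests with edgeR, with rho as a covariate, and with other scalings of the gene lists were chosen after the data were seen; the other settings were fixed before. The number of genes changed was 511 and became 870 with DESeq2 (325 higher and 545 lower, holding 510 of the 511) and 194 at an adjusted p under 0.01 (20 higher and 174 lower, and 194 also in the authors' deposited table at that threshold). DESeq2 gave no adjusted p for 2882 of the 9886 genes tested, among them ddx28, the call it did not hold, so its count is over fewer genes. A change of at least 2-fold left 83 higher genes. Scaling by library totals moved the median of all genes by 0.23 on the log2 scale and gave 415 higher and 252 lower genes, a share of 62.2% higher against 24.5%. Leaving out 1 library gave between 225 and 573 changed genes, between 40 and 125 higher and between 185 and 448 lower; without WT library 1 the count was 311, without WT library 2 it was 225 and without mutant-labelled library 1 it was 279. No called gene turned its direction while staying called in any of the 18 refits. Of 71 named genes that were called, 34 kept the call in all settings run, 17 lost it only when 1 library was left out and 20 lost it in another setting too, with no direction reversed. With edgeR 10 of the 71 lost it. The call of ddx28 was lost in 11 of 17 settings and those of sesn1, nr4a1 and lrit3a in 10 of 18 each. Of 6 genes named outside the rule, mef2cb kept its call in all 18 settings, and lhx4, tpi1a and cx52.9 lost it in settings other than leaving out a library too. The cause was not tested for the counts that moved. The samd7 level kept its call throughout, as did the directions of the opsin shares. The 11 gene lists called became 0 with an estimated correlation and between 10 and 17 with 1 library left out (17 without mutant-labelled library 1). Library totals ended the calls of the p53 and immediate early lists and added that of the lens, and leaving out the low-value filter ended that of the p53 list. The median of the p53 list was -0.13 and became 0.10 under library totals, and that of the visual cycle list, which was not called, became 0.02.

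Replicate numbers are not stated to pair clutches, and the correlation of deviations between same-numbered libraries was 0.05, -0.03 and 0.01. With the replicate number as a block 96 genes were higher and 335 lower, 15 lists were called, and the red and UV shares of opsin differed by -55.1 and 59.5 percentage points (sign-flip exact p = 0.25, the smallest possible). With this block the visual opsin gene opn1sw1 and the visual opsin gene opn1sw2 passed (adjusted p = 0.000129 and 0.000867) and 8 named genes did not. Not every library correlated best with its own number. Depth limits genes near the minimum of 10 normalized counts, where 1 read was worth between 0.747 and 1.33 normalized counts.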

Other observations

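The counts over other groupings of the libraries and the test of a haplotype linked to samd7 were set out before their results were seen, and all other tests below were chosen after. The ratio of opn1sw1 to opn1lw2 was 0.00265, 0.0242 and 0.0263 in libraries 1 to 3 of WT and 1.63, 1.97 and 1.67 in the mutant-labelled libraries. The ratio of arr3b to arr3a was 0.00629, 0.0203 and 0.0216 in WT and 93.5, 90.9 and 54.3 in the mutant-labelled libraries. Within the red opsins, opn1lw1 held 0.183%, 0.115% and 0.0956% in WT and 1.52%, 8.59% and 1.87% in the mutant-labelled libraries.

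The green-cone opsins were at 0 in all mutant-labelled libraries of 18418834, 18956650 and 20369266 reads. A haplotype carried along with samd7 is argued against, since opn1mw1 and opn1mw2 lie on another chromosome in assembly GRCz12tu and the genes changed were not enriched on that of samd7 (odds ratio 1.02, Fisher's exact p = 0.912, 23 of 432 tested genes). Less free RNA from other photoreceptors, with opn1mw1 and rho in the proportions of WT, is argued against too. The lowest WT ratio of opn1mw1 to rho would leave at least 8331 normalized counts in each mutant-labelled library. This ratio cannot decide on a loss of free green-opsin RNA alone, since rho is the rod opsin. A variant or deletion in the opn1mw genes, unlinked to samd7 and carried by the parents of the mutant-labelled clutches, may also keep reads from being counted, and with 0 opn1mw reads and no sequences used here it cannot be told apart from an effect of samd7. The different parents of the groups leave this open.

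UV-cone transcripts were high and arr3a low in the mutant-labelled libraries. UV cones collected in the sort of the mutant-labelled larvae are argued against as the cause of the lower arr3a, which fell further than opn1lw2 by a log2 difference of -4.94 (SE 0.37), with 1.36% of the WT level left for arr3a and 43.2% for opn1lw2. Reads exchanged between arr3a and arr3b in a fixed share are argued against as the cause of their reversed order, because the minor copy held at most 2.16% of the major. A smaller exchange, which could add to the minor copy, was not tested. More free RNA with opn1sw1 and rho rising alike is argued against, because the lowest mutant-labelled ratio of opn1sw1 to rho was 49.3 times the highest in WT. This ratio cannot decide on free RNA from UV cones alone, since rho is the rod opsin. Whether UV cones passed the sort, which would remove cells without the thrb reporter, free RNA of UV cones was carried along, or red cones themselves expressed UV-cone genes cannot be told apart. The log2 change of thrb lay above that of opn1lw2 by 0.89 (SE 0.41), and thrb was at 75.4% of its WT level, a difference that did not pass limma's test.

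Photoreceptor genes were lower and some lists of markers of other cells higher in the mutant-labelled libraries. A lower share of cones in the sort cannot be told apart from a change within cones as the cause of the lower photoreceptor genes. The 50 measured members of the cone phototransduction, outer segment and synapse lists, with arr3a and arr3b left out, differed by more than their errors (Cochran Q against a chi-square reference, p = 1.34e-36, and against 100000 draws of a t reference on 4 degrees of freedom, chosen after that was seen, p = 0.00745, with 15 members beyond 2 SE of the weighted mean of -0.90 and 8 above 0). This spread cannot decide, because members also expressed by other cells would not fall alike with fewer cones. Of the outer segment list, rom1a and rom1b are also on the rod list. A few abundant genes shifting the scaling would move all genes of a library alike. Such a shift is argued against as the whole cause of the lower photoreceptor genes. The cone phototransduction median less the median of all tested genes, in which such a factor cancels, differed by -0.94 (SE 0.18). A lower share of cones may still be the cause of the higher markers of other cells, which cannot be told apart from a change within cones: the effect lay above 0 in 9 of 14 lists of other cells, of which camera called 3 with the preset correlation and 0 with an estimated one. A heterogeneity test asked whether the effects of the lists differed from each other, not whether they lay above 0. Against a chi-square reference its p was 0.949 over the 6 lists of retinal and dividing cells. Over all 14 lists it was 0.0267, where muscle gave 51.9% of the statistic. Against 100000 draws of a t reference on 4 degrees of freedom, chosen after the others were seen, p over the 14 lists was 0.379. The test takes the lists as independent, though they share libraries and some members, such as barhl2, so these p-values cannot decide.

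Of the 10 ways to split the 6 libraries into 3 and 3, only 1, the real one, called as many genes, 511 against at most 2 in the others. For gene lists it was also 1 of 10, with 11 lists against at most 9. With 10 splits the share cannot fall below 0.1. Each other split mixes the genotypes, so a difference between genotypes adds to the spread within its groups and can lower its calls. The counts of the other splits are therefore not a measure of noise alone. The circadian list had a median of -0.77, and the hour at which each clutch was sampled is not in the labels.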
